A study of Mus musculus with 23 samples.

How the data were processed

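RNA was measured in mouse embryos at embryonic day 6.25, shortly after implantation, in 2 compartments, the epiblast (E), which forms the embryo proper, and the extra-embryonic tissue (ExE). The embryos were wild type (wt), heterozygous (Tet1gt/wt) or homozygous (Tet1gt/gt) for a gene trap of Tet1, a dioxygenase that oxidises 5-methylcytosine in DNA. Per the labels' protocols, each library comes from a pool of lysates of at least 6 embryos of 2 to 3 litters, sorted by a genotype read afterwards. The labels give 4 pools per tissue and genotype and state that 1 homozygous ExE pool was lost, which leaves 23 libraries in 6 groups. RNA (1 to 10 ng per pool, RNA integrity number above 8) was turned into cDNA and amplified with the SMARTer Ultra Low Input kit, version 3, made into libraries with NEBNext reagents and read on a NextSeq 500 as single 75-bp reads, per the labels' protocols.

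Per the series' design text and the submitters' processing notes, reads were trimmed with cutadapt 1.7.1 and the FastX tools (0.0.13) and filtered with ShortRead 1.16.3, which removed reads under 35 bp, reads with over 90% A, reads with an N and reads in which over 50% of bases were below Q25. The same notes name TopHat2 2.0.12 and the mouse build mm10 (GRCm38). The program, annotation and strand setting of the counting are not given in the sources used here. The authors deposited 1 table of raw counts per gene, whole numbers that were not normalised, for all 23 libraries. Gene symbols had been altered by a spreadsheet into dates in 27 of its 23725 lines, 4 lines shared a symbol with another line, and 0 lines lacked a gene name. Of the 23723 distinct symbols, 23363 (98.5%) were matched to GENCODE M21 on GRCm38, 828 of them through an older name, to obtain positions, transcript lengths and GC content. Ribosomal protein genes, globin genes, the Rhox and Prl families and other genes with near-identical copies are uncertain, because the counting could divide their reads between copies. A gene and an antisense or overlapping neighbour cannot be told apart without a known strand setting.

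Total counts ranged from 4912215 to 9494814 per library, and 13028 to 14360 genes had at least 1 count. A count of 0 allows up to 3 counts, which is 0.316 to 0.611 CPM (the count relative to the library's total, on the usual scale) depending on the library. That floor covers counting error only, since amplified reads without molecular identifiers are not independent molecules. All 33 pairs of libraries of one group differed by more than counting noise, with a chi-square of 12.3 to 118 per degree of freedom over genes with at least 20 counts. No library thus repeated another, but since amplified reads are not independent this does not show that the pools are. Each library, coming from its own pool, was counted as a replicate. The p-values measure the spread between pools, each of which averages several embryos.

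Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and a quasi-likelihood model was fitted with glmQLFit and tested with glmQLFTest, two-sided. The 3 genotypes of a tissue entered 1 fit, and the tissue comparison and the difference of the genotype effect between tissues came from a fit of all 23 libraries. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. Log2 fold changes use edgeR's prior count of 0.125 and are given ± SE. Levels are TMM-scaled CPM, and log2 CPM levels use a prior count of 2. A gene with every library of a group at 0 is given as a lower bound, computed against the highest CPM that 3 counts stand for in a single library of that group.

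In all, 32 gene lists (cell types, pathways, complexes and sex-linked genes) were fixed in advance and tested with camera from limma 3.58.1, which compares a list with all other genes, at a preset correlation between genes of 0.01 and again with an estimated correlation. A list needed 3 tested members, which left 29 lists in E and 30 in ExE and in the fit of all libraries. The fry test, whose p-value asks whether the genes of a list move on balance in 1 direction without comparing them with other genes, was run beside it. For Tet1, and for 10 comparisons of list levels chosen after the data were seen, two-sided exact permutation tests were used. With 4 against 4 libraries, 2.86% of genes separate completely by chance, and with 3 against 4 libraries 5.71%.

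The genes named follow a rule. Tet1, Tet2, Tet3, 4 DNA methyltransferase genes, Uhrf1 and Jmjd8 are given in the homozygous against wt comparison whatever their p. Up to 10 rises and 10 falls of that comparison, and up to 5 of each in the others, are the largest fold changes among genes past the threshold with a mean log2 CPM of at least 1 and no overlap between groups, a condition that was waived for the difference between tissues. The tissue comparison adds members of the cell type lists. Up to 4 members per list past the threshold are named by smallest p. Where no gene passes, the 3 of smallest p in a direction are named as not passing, and for lists the text prints up to 3 in the list's own direction. Xist, Tsix, Ddx3y, Eif2s3y, Kdm5d and Uty were kept out except as members of a list, and other X-linked genes were treated like the rest. Not every gene that the rule names is reported here. Genes named outside this rule are said to have been chosen after their values were seen. The groups, the tests, the lists, this rule and the alternatives tried were set before the data were examined, apart from the alternatives and tests that the closing section names as chosen later.

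The alternatives set beforehand were size factors by the median-ratio method, no filter and a stricter filter of 1 CPM, DESeq2 1.42.0, limma-voom, the visceral endoderm level or the Y-linked level of each library as a covariate, a test against a fold of 1.5, a fit of only the groups compared, 1 fit of all 23 libraries, the pool number as a block, an estimated correlation for lists, and leaving out each library in turn. Chosen after seeing the data were a fit without 3 libraries that stood apart and a correction of each library for transcript GC content and length by natural splines with 4 degrees of freedom. The labels state that same-numbered E and ExE pools of a genotype share litters in 3 of 4 cases, so the numbers were taken to pair the tissues. All 4 wt numbers occur in both tissues, and which wt pair does not share litters is not given in the sources used here, so 1 wt block may not be a true pair. The correlation of the paired deviations was -0.03 to 0.09 in 4 wt pairs, -0.04 to 0.06 in 3 heterozygous pairs and 0.15 to 0.46 in 3 homozygous pairs. The value of 0.46 was that of homozygous pool 3, whose E and ExE libraries are among the 3 that stood apart. E homozygous pool 3 also correlated at 0.53 with E heterozygous pool 4, which stood apart too. Shared litters and a shared library bias therefore cannot be told apart in that pair. Between genotypes within a tissue only the number is known to be shared, and whether litters were is not given in the sources used here.

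The main test of each of the 8 comparisons was tested on simulated counts, with 200 genes changed by a known fold. Counts were drawn from the real library sizes and, for each gene, its mean over all libraries of the fit and its estimated spread. Each gene was drawn on its own, so a bias shared by many genes of a library was not simulated. For the homozygous against wt comparison in E (12076 genes), 2.99% of genes changed 1.5-fold, 8.96% of those changed 2-fold and 69.2% of those changed 4-fold were recovered, with 0 false calls. DESeq2 recovered 10.4%, 19.4% and 80% with 14 false calls. Limma-voom, the block, the GC and length correction and the fold of 1.5 were simulated for the same comparison, and the block also between tissues. The covariates, the other size factors and filters and the genotype effects in 1 fit of all 23 libraries were not simulated. In ExE (12001 genes) the main test recovered 1.49%, 19.4% and 71.2% with 1 false call. For the difference between tissues (13207 genes) it recovered 0%, 4.48% and 33.3% with 1 false call. Changes of 2-fold or less were therefore mostly out of reach in single genes at this number of pools. For the difference between tissues most 4-fold changes were missed too, and folds between 2 and 4 were not simulated. Mitochondrially encoded genes were not analysed here.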

Results

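The series compares wt, heterozygous and homozygous Tet1 gene-trap embryos in E and in ExE, which asks what the loss of TET1 does in each lineage just after implantation. There were 4 libraries per group except for homozygous ExE, with 3. Total counts per library ranged from 6899786 to 9021097 in E wt, 5764399 to 9452811 in E heterozygous, 5810296 to 9427522 in E homozygous, 7336244 to 9014864 in ExE wt, 6810141 to 9494814 in ExE heterozygous and 4912215 to 7774149 in ExE homozygous. In 3 libraries, E heterozygous 4, E homozygous 3 and ExE homozygous 3, short and GC-rich transcripts read higher than elsewhere. The slope of a gene's deviation on log2 transcript length was -0.42 to -0.38 in these 3, against -0.09 to 0.13 in the other 20 libraries. The slope per 10% of GC content was 0.71 to 0.78 in these 3, against -0.30 to 0.27. The mean log2 CPM of Y-linked genes was -0.14 in ExE wt pool 1, against 3.21 to 3.75 in the other ExE wt pools and 4.98 in E wt pool 1.

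Tet1 transcript was lower in every homozygous pool than in every wt pool of its tissue. Tet1 lies on chromosome 10 from 62804570 to 62908996 on the minus strand (GRCm38). In E its level was 127, 177, 190 and 197 CPM in wt pools 1, 2, 4 and 5, 148, 146, 66.0 and 137 CPM in heterozygous pools 2, 3, 4 and 5, and 69.2, 87.4, 54.9 and 112 CPM in homozygous pools 1, 2, 3 and 4. In ExE it was 110, 98.2, 99.2 and 77.0 CPM in wt pools 1, 2, 4 and 5, 45.8, 50.2, 39.4 and 57.2 CPM in heterozygous pools 1, 2, 3 and 5, and 21.5, 24.1 and 37.7 CPM in homozygous pools 1, 3 and 4. Relative to the wt mean, Tet1 stood at 46.9% ± 14.4 (SD, n = 4) in homozygous E and 28.9% ± 9.10 (SD, n = 3) in homozygous ExE. Heterozygous pools held 71.8% ± 22.6 (SD, n = 4) in E and 50.1% ± 7.82 (SD, n = 4) in ExE. These means include E heterozygous pool 4, E homozygous pool 3 and ExE homozygous pool 3, the libraries with steep length slopes. In E, heterozygous pool 4 and homozygous pool 3 were the lowest of their groups, at 66.0 and 54.9 CPM. Two-sided exact permutation tests gave p = 0.0286 for homozygous E, homozygous ExE and heterozygous ExE, the smallest value these designs allow, and p = 0.114 for heterozygous E. Adjusted over these 4 tests the values were 0.0381 and 0.114. Among all genes, edgeR gave Tet1 a log2 fold change of -1.08 ± 0.28 (adjusted p = 0.92) in homozygous E and -1.79 ± 0.26 (adjusted p = 0.0704) in homozygous ExE. The ExE value passed the threshold by DESeq2 (-1.77, adjusted p = 2.41e-08), with no filter (adjusted p = 0.0252), with all 23 libraries in 1 fit (0.0417), with the GC and length correction (0.027) and without homozygous ExE pool 4 (0.025). Counts cover the gene as a whole, and the site of the trap in Tet1 is not given in the sources used here.

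**Figure D1:**
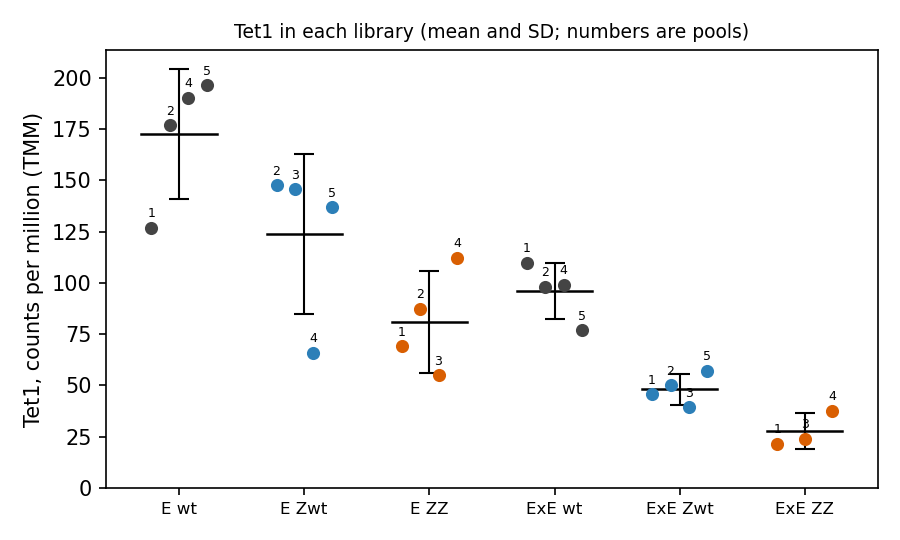
Tet1 in TMM-scaled CPM for each of the 23 libraries, by tissue and genotype (Zwt, heterozygous; ZZ, homozygous), with the pool number beside each point and the mean and SD of each group as a bar. Homozygous pools lie between 54.9 and 112 CPM in E and between 21.5 and 37.7 CPM in ExE, below the wt pools at 127 to 197 and 77.0 to 110 CPM.

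In the homozygous epiblast, Bin1 and Sirpa rose about 3-fold over wt. Bin1, which encodes a BAR-domain protein that bends membranes (chromosome 18, 32377230 to 32435737), was at 31.9 ± 5.58 CPM (SD, n = 4) in wt and 100.3 ± 17.9 CPM (SD, n = 4) in homozygous pools. Its log2 fold change was 1.66 ± 0.19 (edgeR adjusted p = 0.00588), and heterozygous pools were between, at 51.9 ± 1.81 CPM. Sirpa, which encodes a cell-surface receptor for CD47 (chromosome 2, 129592835 to 129632228), went from 18.0 ± 2.51 to 54.4 ± 3.79 CPM, a log2 fold change of 1.60 ± 0.22 (edgeR adjusted p = 0.0281). Heterozygous pools had 29.2 ± 7.84 CPM of Sirpa. For both genes every homozygous pool lay above every wt pool, a separation that chance gives to 2.86% of genes. These were the 2 genes of 12405 that passed the threshold, with 520 at an unadjusted p under 0.05, 17 called by DESeq2 and 2 by limma-voom, and 4 were called without the 3 libraries with steep length slopes. Bin1 missed the threshold without wt pool 5 (adjusted p = 0.0577). With the pool number as a block both genes missed it (edgeR adjusted p = 0.398 for Bin1 and 0.9996 for Sirpa). Sirpa missed it whenever any single wt or homozygous pool was left out (adjusted p = 0.0597 to 0.212), and with the visceral endoderm level as a covariate (0.0671), with the Y-linked level as a covariate (0.0742), in the fit of all 23 libraries (0.984) and against a fold of 1.5 (0.188), where Bin1 also missed it (0.0728).

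No gene passed the threshold downwards in the homozygous epiblast. The 3 falls of smallest p, none past the threshold, were Nnat, an imprinted gene (-1.23 ± 0.24, edgeR adjusted p = 0.362), Lefty2, an inhibitor of Nodal signalling (-1.97 ± 0.43, 0.488), and Rsbn1 (-1.43 ± 0.35, 0.753). Nnat was at 46.0 ± 11.3 CPM in wt and 19.5 ± 3.93 CPM in homozygous pools, and Lefty2 at 33.1 ± 11.9 and 8.31 ± 3.57 CPM (SD, n = 4 each). Jmjd8, which the study itself singled out on these samples and which is therefore no independent evidence, was at 14.4 ± 3.05 CPM in wt and 6.48 ± 0.981 CPM in homozygous E (log2 fold change -1.14 ± 0.31, edgeR adjusted p = 0.961). The other enzymes of DNA methylation did not pass the threshold (edgeR adjusted p of 0.961 or more). Tet2 stood at 0.37 ± 0.99 and Tet3 at 0.19 ± 0.28 on the log2 scale, the maintenance genes Dnmt1 and Uhrf1 at -0.16 ± 0.19 and -0.01 ± 0.13, and the de novo genes Dnmt3a, Dnmt3b and Dnmt3l at 0.02 ± 0.15, -0.33 ± 0.17 and -0.28 ± 0.46. DESeq2 called further genes, of which the following were chosen after their values were seen. Cd44, a hyaluronan receptor, was at 1.36 ± 0.347 CPM in wt and 14.5 ± 1.66 CPM in homozygous E (DESeq2 log2 fold change 3.43, adjusted p = 2.6e-05). Barx1, a homeobox gene, was at 0.217 ± 0.186 and 8.24 ± 3.19 CPM (5.22, 1.48e-06), and Twist1, a regulator of mesenchyme, at 1.78 ± 1.22 and 9.99 ± 2.26 CPM. Crabp2, a retinoic acid carrier, was at 19.3 ± 4.36 and 40.4 ± 5.88 CPM.

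**Figure D2:**
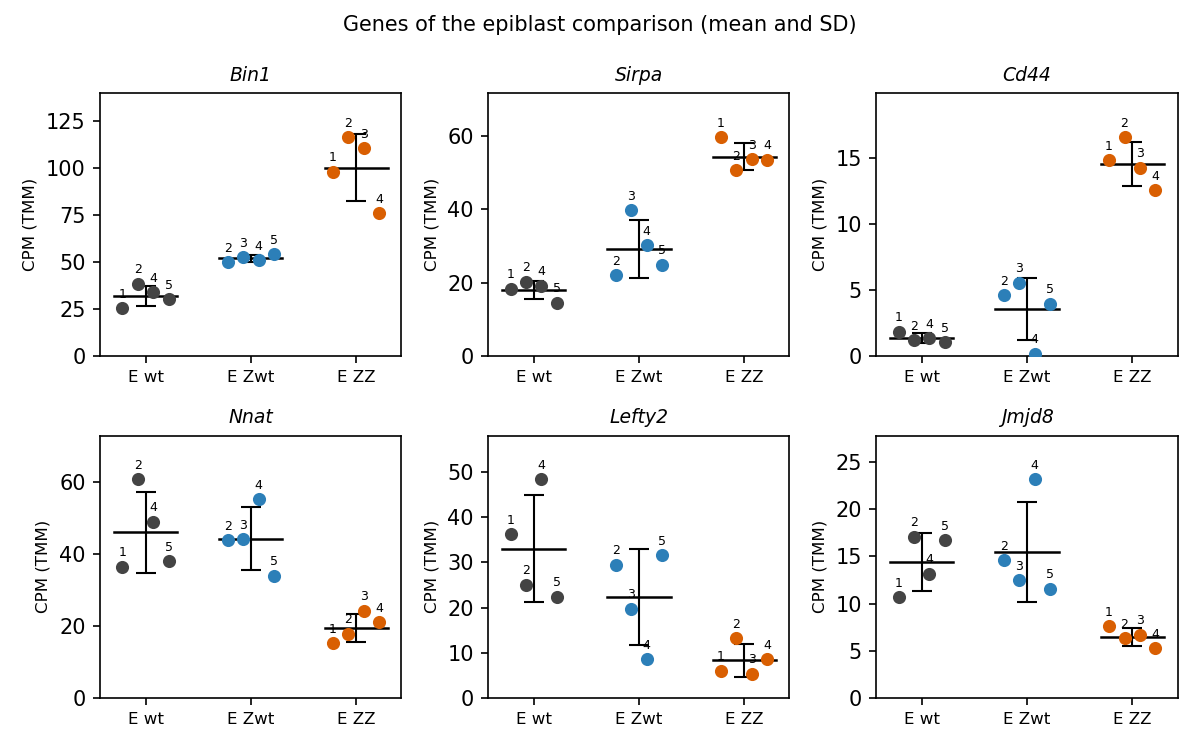
TMM-scaled CPM of 6 genes in the 12 epiblast libraries, by genotype (Zwt, heterozygous; ZZ, homozygous), with pool numbers, group mean and SD. Bin1 and Sirpa passed the threshold in homozygous against wt (edgeR adjusted p = 0.00588 and 0.0281), and Cd44, Nnat, Lefty2 and Jmjd8 did not.

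Among the gene lists, primitive streak and mesoderm genes fell in homozygous E, cholesterol biosynthesis genes fell, and ribosomal protein and oxidative phosphorylation genes rose. Of 17 primitive streak and mesoderm genes, 15 were lower (median log2 fold change -0.53, camera adjusted p = 1.83e-05, and adjusted p = 0.657 with an estimated correlation). None passed over all genes, and 3 fell when adjusted over the list alone. By mean log2 CPM the groups overlapped (exact permutation p = 0.314, 0.349 adjusted over 10 such tests), with wt pools 1 and 4 at 3.88 and 4.11, wt pools 2 and 5 at 2.50 and 2.02 and homozygous pools at 2.10 to 3.06. Mixl1, a homeobox gene of the streak, was at 60.5 ± 59.2 CPM in wt and 5.94 ± 4.08 CPM in homozygous pools, Mesp1, a regulator of early mesoderm, at 14.8 ± 17.4 and 0.112 ± 0.224 CPM, and Lefty2 as above. Of 25 cholesterol biosynthesis genes, 22 were lower (median -0.23, adjusted p = 0.0118, and adjusted p = 0.657 with an estimated correlation), 0 of them called over all genes or adjusted over the list alone. Its smallest p-values belonged to Lss (-0.76 ± 0.33), Nsdhl (-0.60 ± 0.28) and Acat2 (-0.23 ± 0.12), each with an edgeR adjusted p of 0.961. That call was lost without wt pool 2 (adjusted p = 0.0764) and without homozygous pool 2 (0.103). All 79 ribosomal protein genes were higher (median 0.51, adjusted p = 9.49e-18, and adjusted p = 0.657 with an estimated correlation), with Rpl41 at 1.25 ± 0.60, Rpl35a at 0.83 ± 0.37 and Rpl29 at 0.57 ± 0.28. Of 69 oxidative phosphorylation genes, 64 were higher (median 0.40, adjusted p = 2.27e-08, and adjusted p = 0.765 with an estimated correlation), with Atp5e at 1.11 ± 0.49, Uqcrh at 0.68 ± 0.33 and Ndufs4 at 0.56 ± 0.27. In these 2 lists 0 genes were called over all genes or adjusted over the list alone. Both moved with the library apart from the rest. The mean log2 CPM of ribosomal protein genes was 9.47 in homozygous pool 3, 8.31 to 8.38 in the other homozygous pools and 8.00 to 8.38 in wt. Without homozygous pool 3 the oxidative phosphorylation call was lost (adjusted p = 0.293), as it was without all 3 libraries with steep length slopes (0.0647). The medians were 0.13 for cytosolic ribosomal protein genes and 0.056 for oxidative phosphorylation genes without that pool, and 0.20 and 0.10 with the GC and length correction. Without wt pool 1 the median of primitive streak and mesoderm genes was -0.31, and that of cholesterol biosynthesis genes was -0.14 and -0.35 without homozygous pools 2 and 4.

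**Figure D3:**
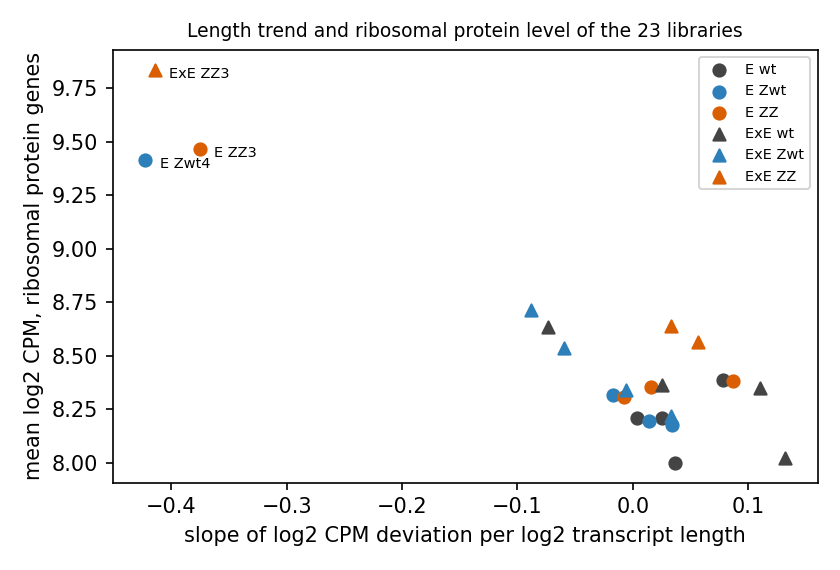
Mean log2 CPM of the ribosomal protein genes against the slope of a gene's log2 CPM deviation per log2 transcript length, 1 point per library, by tissue (circles E, triangles ExE) and genotype (colours). The 3 named libraries have slopes of -0.42 to -0.38, the others -0.09 to 0.13.

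In homozygous ExE no single gene passed the threshold in edgeR (0 of 12355, with 935 at an unadjusted p under 0.05, 16 called by DESeq2 and 0 by limma-voom). After Tet1, the falls of smallest p were Rnf40, a ubiquitin ligase that acts on histone H2B (-0.78 ± 0.18), and Cd97, an adhesion receptor (-1.41 ± 0.33). The rises of smallest p were Rpl22l1, a ribosomal protein paralogue (0.94 ± 0.21), Uqcrb, a subunit of respiratory complex III (0.97 ± 0.22), and Polr2k, a subunit shared by RNA polymerases (1.15 ± 0.27). All 5 had an edgeR adjusted p of 0.513. Dnmt3b was at 2386 ± 698 CPM in wt and 1675 ± 244 CPM in homozygous ExE (-0.52 ± 0.19, adjusted p = 0.548). The other named regulators had log2 fold changes of 0.50 ± 0.29 (Tet3), -0.12 ± 0.43 (Tet2), -0.21 ± 0.19 (Dnmt1), -0.13 ± 0.15 (Uhrf1), -0.31 ± 0.49 (Dnmt3a) and 0.22 ± 0.25 (Dnmt3l), with adjusted p of 0.729 or more by edgeR. Jmjd8 was at 6.87 ± 1.85 CPM in wt and 6.95 ± 2.14 CPM in homozygous ExE. Phlda2, an imprinted gene that restrains placental growth and was chosen after its values were seen, was at 187 ± 51.6 CPM in wt, 404 ± 156 in heterozygous and 684 ± 454 CPM in homozygous ExE (DESeq2 log2 fold change 1.89 for homozygous against wt, adjusted p = 0.0347).

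Of the lists in homozygous ExE, maternal decidua genes, ribosomal protein genes and oxidative phosphorylation genes rose, and Nodal and FGF pathway genes fell. Of 8 decidua genes 7 were higher (median 2.44, camera adjusted p = 0.00116, and adjusted p = 0.352 with an estimated correlation), 0 of them called over all genes and 1 adjusted over the list alone. Prl8a2, a prolactin-family gene of the decidua, was at 13.2, 174 and 17.5 CPM in homozygous pools 1, 3 and 4, against 3.61 ± 5.05 CPM in wt (log2 fold change 4.20 ± 1.27), and Prl3c1 differed by 4.23 ± 1.59 and Cryab by 2.36 ± 0.98. Of 23 FGF and ERK pathway genes 19 were lower (median -0.42, adjusted p = 0.0282, and adjusted p = 0.686 with an estimated correlation), with Dusp5 at -1.15 ± 0.35, Etv5 at -0.54 ± 0.26 and Spred2 at -0.56 ± 0.32. Of 21 Nodal and TGF-beta pathway genes 14 were lower (median -0.24, adjusted p = 0.0318, and adjusted p = 0.352 with an estimated correlation), with Smad4 at -0.65 ± 0.23, Lefty1 at -2.89 ± 1.11 and Acvr1b at -1.55 ± 0.61. Neither list had a gene called over all genes or adjusted over the list alone. The FGF call was lost without wt pool 4 (adjusted p = 0.0919), wt pool 5 (0.0768) or homozygous pool 1 (0.537) and with the GC and length correction (0.051). The Nodal call was lost without wt pool 1 (0.1), wt pool 4 (0.126), wt pool 5 (0.0801) or homozygous pool 1 (0.304) and with that correction (0.0907). All 79 ribosomal protein genes were higher (median 0.73, adjusted p = 3.53e-44, and adjusted p = 0.352 with an estimated correlation; 69 adjusted over the list alone), Rpl37a by 1.45 ± 0.39, Rpl34 by 1.37 ± 0.34 and Rpl39 by 1.25 ± 0.32. Of 69 oxidative phosphorylation genes 63 were higher (median 0.79, adjusted p = 3.01e-30, and adjusted p = 0.352 with an estimated correlation; 38 adjusted over the list alone), Atp5e by 1.71 ± 0.42 and Cox6c by 0.88 ± 0.22. No gene of either list was called over all genes. The ribosomal level was 9.84 in homozygous pool 3, 8.57 to 8.64 in the other homozygous pools and 8.02 to 8.64 in wt. The medians were 0.24 for cytosolic ribosomal protein genes and 0.18 for oxidative phosphorylation genes without homozygous pool 3, and 0.34 and 0.28 with the GC and length correction. That of FGF and ERK pathway genes was -0.27, -0.20 and -0.65 without wt pool 1 and homozygous pools 1 and 4. That of Nodal and TGF-beta pathway genes was -0.39 and -0.48 without homozygous pools 3 and 4, and -0.15 with the correction.

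Heterozygous epiblast had far less of the visceral endoderm transcripts than wt epiblast. Of 25 markers of that layer, which encloses the epiblast, 24 were lower (median log2 fold change -3.57, camera adjusted p = 3.89e-16, and adjusted p = 0.76 with an estimated correlation), 0 called over all genes and 18 adjusted over the list alone. Without wt pool 1, where the mean log2 CPM of visceral endoderm markers was 5.78 against 1.47 to 3.08 in the other wt pools, the median was -1.45 (camera adjusted p = 4.50e-08, and adjusted p = 0.961 with an estimated correlation). Apob, an apolipoprotein, was at 18.2 ± 19.9 CPM in wt and 0.0871 ± 0.174 CPM in heterozygous pools (SD, n = 4). Cubn, an endocytic receptor, was at 26.0 ± 46.1 and 0.324 ± 0.506 CPM. Afp, alpha-fetoprotein, had 0 counts in all 4 heterozygous pools and was at least 15.4-fold lower than the wt mean of 7.99 CPM. The mean log2 CPM of the list was 3.00 ± 1.98 in wt, 0.68 ± 0.52 in heterozygous and 2.95 ± 1.75 in homozygous E. The heterozygous against wt difference had an exact permutation p of 0.0286 (0.0714 adjusted over 10 such tests).

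No gene was called in heterozygous E against wt by edgeR (0 of 12405, with 298 at an unadjusted p under 0.05, 4 by DESeq2 and 0 by limma-voom). Among the rises of smallest p were Bin1 (0.71 ± 0.19) and Barx1 (2.97 ± 0.80). Falls of smallest p were Apob, Herc6, a ubiquitin ligase family member (-3.00 ± 0.62), and Vegfa, an endothelial growth factor (-1.48 ± 0.36), and each of these had an edgeR adjusted p of 0.982. Ribosomal protein genes rose as a list (79 of 79 higher, median 0.41, camera adjusted p = 2.09e-14, and adjusted p = 0.86 with an estimated correlation), with Rplp0 at 0.57 ± 0.29 and Rps3 at 0.41 ± 0.21. Oxidative phosphorylation genes also rose (67 of 69 higher, median 0.38, adjusted p = 2.07e-10, and adjusted p = 0.86 with an estimated correlation), with Uqcrh at 0.66 ± 0.33 and Ndufb8 at 0.61 ± 0.32. The ribosomal level was 9.42 in heterozygous pool 4, and without that pool both calls were lost (adjusted p = 0.352 and 0.531), as they were without all 3 libraries with steep length slopes (0.108 and 0.346). The 4 Y-linked genes were lower (median -0.71, adjusted p = 0.00839, and adjusted p = 0.76 with an estimated correlation), among them Uty (-0.84 ± 0.55) and Kdm5d (-0.96 ± 0.68), and the call was lost without heterozygous pool 3 (0.14) or pool 4 (0.11) and without all 3 of those libraries (0.0839). The medians were 0.025 for cytosolic ribosomal protein genes and 0.022 for oxidative phosphorylation genes without heterozygous pool 4, and 0.10 and 0.095 with the GC and length correction. That of Y-linked genes was -1.29 and -0.41 without heterozygous pools 2 and 4. Pools may hold different shares of males, so the Y-linked fall is not shown to be an effect of genotype. In these 3 lists 0 genes were called over all genes or adjusted over the list alone.

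Heterozygous ExE differed from wt in 9 lists, with lower levels of transcripts typical of the epiblast. Of 24 epiblast markers 22 were lower (median -0.62, camera adjusted p = 9.96e-07, and adjusted p = 0.536 with an estimated correlation), 4 of them adjusted over the list alone. The mean log2 CPM of the list was 5.70 ± 0.85 in wt and 5.02 ± 0.35 in heterozygous ExE, with overlap (exact permutation p = 0.229, 0.286 adjusted over 10 such tests). Sall2, a zinc-finger gene, was at 25.6 ± 18.4 CPM in wt and 5.33 ± 2.91 CPM in heterozygous ExE (-2.23 ± 0.57), Dnmt3b changed by -0.64 ± 0.18 and Etv5 by -0.85 ± 0.24. Anterior visceral endoderm markers (9 of 10 lower, median -1.74, adjusted p = 0.000549), FGF and ERK pathway genes (21 of 23, -0.40, 0.000549), Nodal and TGF-beta genes (17 of 21, -0.37, 0.00155), primitive streak and mesoderm genes (12 of 16, -0.87, 0.00392) and WNT genes (16 of 20, -0.26, 0.0147) also fell. With an estimated correlation their adjusted p was 0.582, 0.536, 0.536, 0.67 and 0.536. Among their members were Fzd8 (-2.50 ± 0.84), Lhx1 (-4.94 ± 1.68), Lefty1 (-2.40 ± 0.94), Fgf15 (-3.48 ± 1.06), Fgf8 (-1.69 ± 0.63), Apln (-2.43 ± 1.02), Nodal (-2.15 ± 0.94), Pmepa1 (-1.10 ± 0.48), Lef1 (-2.38 ± 0.82) and Nkd1 (-1.69 ± 0.88). Extra-embryonic ectoderm markers rose (16 of 21 higher, median 0.10, adjusted p = 0.00155, and adjusted p = 0.598 with an estimated correlation), with Tfap2c at 0.71 ± 0.31, Rhox9 at 0.81 ± 0.37 and Ascl2 at 1.23 ± 0.57. Ribosomal protein genes (78 of 79 higher, 0.12, 0.00147) and oxidative phosphorylation genes (65 of 69, 0.13, 0.00155) rose slightly, with adjusted p = 0.936 for both with an estimated correlation. Their members of smallest p included Rpl5 (0.22 ± 0.13), Rps27a (0.27 ± 0.20), Atp5f1 (0.26 ± 0.15) and Uqcrb (0.36 ± 0.21). Apart from the epiblast list, 0 genes of these lists were called adjusted over the list alone.

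Several of these list calls in heterozygous ExE rested on single pools. Without wt pool 1 the extra-embryonic ectoderm, ribosomal and oxidative phosphorylation calls were lost (adjusted p = 0.365, 0.505 and 0.274), and without heterozygous pool 1 the last 2 (0.492 and 0.213). The primitive streak call was lost without wt pool 4 (0.166) or heterozygous pool 2 (0.0605), and the WNT call without heterozygous pool 2 (0.155). With the GC and length correction the WNT, ribosomal and oxidative phosphorylation calls were lost (0.071, 0.303 and 0.302). Without wt pool 1 the medians were -0.33 for epiblast markers, -0.19 for Nodal and TGF-beta pathway genes, -0.23 for FGF and ERK pathway genes, -0.020 for extra-embryonic ectoderm markers, 0.028 for cytosolic ribosomal protein genes and 0.044 for oxidative phosphorylation genes. The ribosomal and oxidative phosphorylation medians were 0.015 and 0.045 without heterozygous pool 1, 0.22 and 0.19 without wt pool 4, and the ribosomal one 0.19 without heterozygous pool 2. The extra-embryonic ectoderm median was 0.24, 0.17 and 0.066 without wt pools 2 and 5 and heterozygous pool 5. Without heterozygous pool 3 that of primitive streak and mesoderm genes was -0.55 and that of FGF and ERK pathway genes -0.25. With the correction the extra-embryonic ectoderm, Nodal, FGF, ribosomal and oxidative phosphorylation medians were 0.22, -0.24, -0.26, 0.067 and 0.077. By gene, edgeR called 0 of 12355, with 510 at an unadjusted p under 0.05, 18 called by DESeq2 and 0 by limma-voom. The fit of all 23 libraries called 20 genes, all of them lower. Falls of smallest p were Shc2, a signalling adaptor (-4.93 ± 1.02), Ncs1, a neuronal calcium sensor (-1.81 ± 0.39), and Ccnd2, cyclin D2 (-2.47 ± 0.55). Rises were Pccb, a subunit of propionyl-CoA carboxylase (1.13 ± 0.28), Arhgap8 (1.42 ± 0.37) and Ppp1r3b, a glycogen-targeting phosphatase subunit (2.80 ± 0.82), with edgeR adjusted p of 0.891 to 0.943 for these 6. Ccnd2 was at 9.83 ± 5.27 CPM in wt and 1.73 ± 0.687 CPM in heterozygous ExE.

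**Figure D4:**
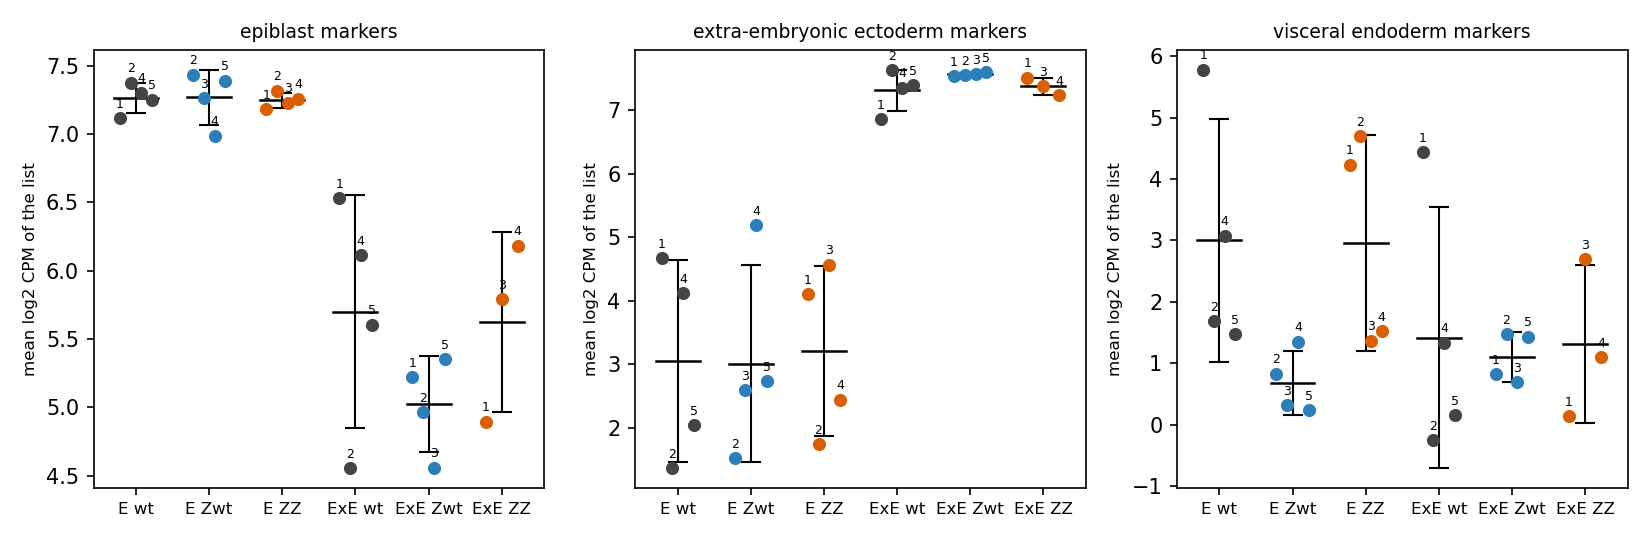
Mean log2 CPM of the markers of epiblast, extra-embryonic ectoderm and visceral endoderm in each of the 23 libraries, by tissue and genotype (Zwt, heterozygous; ZZ, homozygous), with pool numbers, group mean and SD. The visceral endoderm level in E was 3.00 ± 1.98 in wt and 0.68 ± 0.52 in heterozygous pools.

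Homozygous against heterozygous epiblast showed the visceral endoderm difference from the other side. Of 25 visceral endoderm markers 24 were higher in homozygous E (median 3.00, or 2.79 with genes at 0 set to their bound, camera adjusted p = 2.04e-21, and adjusted p = 0.347 with an estimated correlation), 0 called over all genes and 9 adjusted over the list alone. Afp was at least 27.1-fold higher, and Cubn differed by 4.87 ± 1.48. Anterior visceral endoderm markers rose (11 of 12 higher, 2 adjusted over the list alone, median 0.57, adjusted p = 0.00152, and adjusted p = 0.556 with an estimated correlation). Among them Cer1, a secreted Nodal inhibitor, was at least 16.1-fold higher, and Sfrp1 differed by 0.69 ± 0.27. Dkk1, a WNT inhibitor, was at 0.0266 ± 0.0532 CPM in heterozygous and 6.55 ± 7.83 CPM in homozygous E. Parietal endoderm markers rose (10 of 12, median 0.43, adjusted p = 0.00154, and adjusted p = 0.556 with an estimated correlation), with Srgn at 4.41 ± 1.45, Vim at 0.58 ± 0.22 and Lama1 at 1.81 ± 0.93. Primitive streak and mesoderm genes fell (14 of 17, median -0.50, adjusted p = 0.00154, and adjusted p = 0.556 with an estimated correlation), with Mixl1 at -2.11 ± 0.80, Mesp1 at -4.66 ± 1.69 and Lefty2 at -1.42 ± 0.42. Cholesterol genes fell (21 of 25, median -0.21, adjusted p = 0.00152, and adjusted p = 0.347 with an estimated correlation), with Tm7sf2 at -0.93 ± 0.45 and Sc5d at -0.59 ± 0.31. In these last 3 lists 0 genes were called adjusted over the list alone. The anterior call was lost without homozygous pool 2 (adjusted p = 0.313), the parietal call without homozygous pool 1 (0.108) and the streak call without homozygous pool 3 (0.0608). The median of anterior visceral endoderm markers was 0.89 without heterozygous pool 2 and 0.87 without homozygous pool 3, and that of parietal endoderm markers 0.26 without homozygous pool 1. By gene, edgeR called 0 of 12405, with 308 at an unadjusted p under 0.05, 6 by DESeq2 and 0 by limma-voom. The rises of smallest p were Cald1, caldesmon (0.93 ± 0.18), Bin1 (0.95 ± 0.19) and Apob. The falls were Nnat (-1.18 ± 0.24), Nr1d1, a nuclear receptor of the clock (-1.20 ± 0.29), and Jmjd8 (-1.24 ± 0.31), all with an edgeR adjusted p of 0.906 or more.

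In homozygous against heterozygous ExE, epiblast markers rose (17 of 24 higher, median 0.32, camera adjusted p = 0.026, and adjusted p = 0.629 with an estimated correlation) and extra-embryonic ectoderm markers fell (15 of 21 lower, median -0.23, adjusted p = 0.0152, and adjusted p = 0.614 with an estimated correlation). Pou5f1, the pluripotency factor OCT4, differed by 2.27 ± 0.78, Sall2 by 1.94 ± 0.60 and Tdgf1 by 1.60 ± 0.57, and Cdx2, a trophoblast regulator, by -0.50 ± 0.19, Zfp42 by -0.57 ± 0.30 and Bmp8b by -0.50 ± 0.27. Decidua genes rose (8 of 8, median 2.84, adjusted p = 9.73e-05, and adjusted p = 0.247 with an estimated correlation), with Prl8a2 at 3.65 ± 1.23 and Prl3c1 at 4.40 ± 1.60. Ribosomal protein genes (79 of 79, median 0.63, adjusted p = 9.03e-29) and oxidative phosphorylation genes (62 of 69, median 0.64, adjusted p = 3.55e-18) rose, with adjusted p = 0.614 for both with an estimated correlation. Rpl37a differed by 1.39 ± 0.39, Rpl39 by 1.13 ± 0.32, Atp5l by 1.37 ± 0.39 and Cox7c by 0.94 ± 0.27. In these 5 lists 0 genes were called over all genes or adjusted over the list alone. The epiblast call was lost without heterozygous pool 2 (adjusted p = 0.0572) or 3 (0.205) and homozygous pool 3 (0.24) or 4 (0.705). The extra-embryonic ectoderm call was lost without homozygous pool 4 (0.202) and the oxidative phosphorylation call without homozygous pool 3 (0.247), the only 1 of the 3 libraries with steep length slopes in this fit. Without that pool the medians were 1.58 for maternal decidua genes, 0.11 for cytosolic ribosomal protein genes and 0.054 for oxidative phosphorylation genes, the last 2 being 0.28 and 0.18 with the GC and length correction. That of epiblast markers was 0.21 without heterozygous pool 3 and 0.18 without homozygous pool 4. By gene, edgeR called 0 of 12355, with 800 at an unadjusted p under 0.05, 8 by DESeq2 and 0 by limma-voom. The rises of smallest p were Siglec1, Zfp935 and Xaf1 (2.70 ± 0.60, 2.13 ± 0.48 and 2.92 ± 0.66), and the falls were Pccb (-1.34 ± 0.32), Polg, the mitochondrial DNA polymerase (-0.74 ± 0.21), and Tbc1d1 (-1.07 ± 0.30), each with an edgeR adjusted p of 0.73. Siglec1 was at 49.1, 83.1 and 86.9 CPM in the 3 libraries with the steep length slope, against 3.30 to 26.6 CPM in the other 20.

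Between the wt tissues the differences were large, and 2347 of 13595 genes passed the threshold, 1262 higher and 1085 lower in ExE than in E. Of these, 1849 differed more than 2-fold, 989 of them higher and 860 lower in ExE, and 2168 had no overlap between pools. DESeq2 called 2983 and limma-voom 3093. All 21 extra-embryonic ectoderm markers were higher in ExE (median log2 fold change 3.78, camera adjusted p = 1.27e-19, and adjusted p = 0.188 with an estimated correlation). Ets2, a trophoblast transcription factor, rose by 2.54 ± 0.30 from 32.1 ± 7.23 to 187 ± 64.7 CPM, Fgfr2, a receptor for FGF, by 3.78 ± 0.53, Ddah1 by 3.21 ± 0.45 and Satb1 by 1.46 ± 0.23. Of 24 epiblast markers, 15 fell and 0 rose over all genes, and 15 fell and 3 rose adjusted over the list alone (median -1.45, adjusted p = 1.06e-07, and adjusted p = 0.281 with an estimated correlation). Dnmt3b, the main de novo methyltransferase of the epiblast, changed by -1.58 ± 0.19 from 7116 ± 703 to 2386 ± 698 CPM, Etv5 by -1.33 ± 0.22, Sall2 by -2.23 ± 0.43, Tdgf1, a Nodal co-receptor, by -2.39 ± 0.46 and Fgf5 by -3.17 ± 0.72. Of 18 immediate early genes, which respond within minutes to stimulation, 10 rose over all genes and 12 adjusted over the list alone (median 1.65, adjusted p = 1.03e-05, and adjusted p = 0.188 with an estimated correlation). Among them were Junb (3.17 ± 0.56), Nr4a1 (3.03 ± 0.51) and Dusp1 (1.55 ± 0.21). All genes named as rising or falling here had an edgeR adjusted p of 0.0463 or less.

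Other lists held members that passed the threshold between tissues without a call for the list. Of 15 naive pluripotency genes 7 rose and 2 fell in ExE (camera adjusted p = 0.053), among them Klf5 (3.82 ± 0.57), Klf2 (4.33 ± 0.82), Zfp42 (3.44 ± 0.66) and Esrrb (4.65 ± 0.94), which extra-embryonic ectoderm also uses. In the BMP pathway 6 of 18 rose and 3 fell, with Bmp8b at 4.46 ± 0.85, Id2 at 3.73 ± 0.73 and Bmp4 at 3.68 ± 0.79. In the Nodal and TGF-beta pathway 3 of 21 rose, among them the convertase gene Pcsk6 (3.08 ± 0.36), and 7 fell, among them Lefty2 (-2.92 ± 0.82). Among imprinted genes 10 of 45 rose, with Gab1 at 3.30 ± 0.55 and Slc38a4 at 1.88 ± 0.32, and 6 fell, with Gnas at -1.01 ± 0.15 and Cd81 at -1.12 ± 0.19. Of 24 glycolysis genes 5 rose, including Hk1 (2.70 ± 0.31) and Pfkp (2.38 ± 0.42), and 2 fell. Ectoplacental cone markers Fosl1 (4.99 ± 1.30), Hand1 (4.40 ± 1.37) and Plac1 (3.85 ± 1.31) rose, and Otx2 (-2.55 ± 0.61), Mixl1 (-3.40 ± 0.75) and Lrp2 (-2.44 ± 0.71) fell. The Plac1 call was lost by limma-voom (adjusted p = 0.347) and without any 1 of E or ExE wt pools 2, 4 and 5 (edgeR adjusted p = 0.0763 to 0.122). The Hand1 call was lost without E wt pools 2, 4 or 5 or ExE wt pool 2 (0.0638 to 0.0852), that of Lrp2 without E wt pool 4 or ExE wt pools 4 or 5 (0.0515 to 0.0657), that of Lefty2 without ExE wt pool 2 (0.0532) and that of Mixl1 by limma-voom (0.0508). With the Y-linked level as a covariate Fosl1 (0.0522), Hand1 (0.212), Plac1 (0.0674), Mixl1 (0.0658), Lefty2 (0.153) and Sh3gl2 (0.0774) missed the threshold, and against a fold of 1.5 Hand1 (0.0519) and Plac1 (0.0836) did. Of the methylation genes, Dnmt3l rose by 2.74 ± 0.40 and Dnmt3a changed by -2.29 ± 0.38. The rises that edgeR ranked highest by fold were Klf14, Npas2, Tnnt3, Tnip2 and Rhox2e. They had 0 counts in every E wt pool, so their rank depends on the prior count and is not shown by the counts. They were at least 14.7, 12.4, 9.66, 8.11 and 6.72-fold higher in ExE. Among the falls that edgeR ranked highest by fold, Kctd12b changed by -6.02 ± 1.04 and Sh3gl2 by -5.92 ± 1.42. Lhfpl4 and the glutamate receptor gene Gria3, also ranked there, had 0 counts in every ExE wt pool and were at least 10.4 and 3.09-fold lower, so their rank is not shown either. The calcium channel gene Cacnb2 was at 6.48 ± 3.51 CPM in E and 0.0338 ± 0.0675 CPM in ExE. The count of 2347 was 1502 without ExE wt pool 2 and 3672 in a fit without the 3 libraries with steep length slopes, which hold no wt pool but enter the estimate of the spread. With the pool number as a block, 8 lists were called in place of 3. Fry, adjusted over the lists, called 10 lists in this comparison and 0 in the others. In the lists called in any comparison, the median, the mean and the test had the same sign.

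The effect of homozygosity was also compared between tissues directly. By this test oxidative phosphorylation genes (median difference 0.35, camera adjusted p = 0.000182) and cytosolic ribosomal protein genes (0.26, 0.0013) rose more in ExE than in E, with Uqcrb at 0.87 ± 0.37, Atp5j at 0.50 ± 0.37, Rpl34 at 0.70 ± 0.61 and Rps25 at 0.51 ± 0.42. With an estimated correlation the adjusted p was 0.936 for both. FGF and ERK pathway genes were lower in ExE relative to E (median -0.23, adjusted p = 0.0374, and adjusted p = 0.933 with an estimated correlation), with Dusp5 at -1.67 ± 0.69 and Etv4 at -0.73 ± 0.45. The 4 Y-linked genes were higher (1.02, 0.045, and adjusted p = 0.933 with an estimated correlation), with Uty at 1.17 ± 1.09 and Kdm5d at 1.22 ± 1.34. Pools may hold different shares of males, so the Y-linked difference is not shown to be an effect of genotype. In these 4 lists 0 genes were called over all genes or adjusted over the list alone. Without ExE homozygous pool 3 both the ribosomal and the oxidative phosphorylation differences turned downwards (adjusted p = 0.102 and 0.448), and without ExE wt pool 1 both calls were lost (0.238 and 0.0543). The ribosomal call was also lost without E wt pool 5 (0.0745) and E homozygous pools 1 (0.134), 2 (0.108) and 4 (0.0841). The FGF call was lost without E wt pool 5 (0.0857), E homozygous pools 1 (0.0528) and 3 (0.0706), ExE wt pools 1 (0.18), 4 (0.0779) and 5 (0.0518) and ExE homozygous pools 1 (0.486) and 3 (0.13). The Y-linked call was lost without E wt pools 2 (0.0547), 4 (0.081) and 5 (0.0745), E homozygous pools 2 (0.0818) and 3 (0.18), ExE wt pool 1 (0.435) and ExE homozygous pools 1 (0.367) and 4 (0.125), and with the GC and length correction (0.0895). Without the 3 libraries with steep length slopes the FGF call was lost (0.0786), and the median differences of the oxidative phosphorylation and ribosomal lists were 0.13 and 0.09. With the GC and length correction these were 0.20 and 0.13, and without E homozygous pool 3 they were 0.72 and 0.63. Without ExE homozygous pools 1 and 4 the oxidative phosphorylation median was 0.56 and 0.58, and the ribosomal one 0.46 and 0.47. The ribosomal median was also 0.17, 0.14 and 0.17 without E homozygous pools 1, 2 and 4, and 0.16 and 0.39 without ExE wt pools 1 and 4. That of FGF and ERK pathway genes was -0.43, -0.53, -0.41 and -0.61 without E wt pool 1, ExE wt pools 2 and 5 and ExE homozygous pool 4, and that of Y-linked genes 0.62 and 0.36 without ExE wt pool 1 and ExE homozygous pool 1. With the pool number as a block the Y-linked call was lost (0.0592), and with the GC and length correction in that fit so were the FGF (0.0632) and ribosomal calls (0.0876). No gene was called by edgeR (0 of 13595, with 416 at an unadjusted p under 0.05, 3 by DESeq2 and 0 by limma-voom). Itga3, an integrin subunit, differed by -1.30 ± 0.27 (edgeR adjusted p = 0.63, DESeq2 adjusted p = 0.0138). 1700047I17Rik2 (1.13 ± 0.30), Mixl1 (3.54 ± 1.05) and Pcnx (-1.38 ± 0.35) followed, with an edgeR adjusted p of 1.00, and Zfp786 and Emilin3 are given no fold because 1 group had no counts. The call of a gene in 1 tissue and not in the other is therefore not shown to differ between tissues.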

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

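Of the tests in this part, those of Bin1 and Sirpa, of the ribosomal protein list without single libraries and of the visceral endoderm list were chosen after the result was seen. The prediction for length and GC slopes was written before the slopes were seen, but the 3 libraries it concerns were picked after the data were seen. The counts over other splits of the pools were set beforehand.

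Each group of 4 libraries was tested for a library far from the others, in its total count, in Tet1, Jmjd8, Bin1 and Sirpa and in the level of each list called in a genotype comparison. Of 95 such tests 6 found one, where chance at 1 in 20 gives 4.75. Tet1 in E heterozygous pool 4 was 66.0 CPM, with the nearest other pool at 137 CPM. That pool and E homozygous pool 3 also stood out in oxidative phosphorylation genes (mean log2 CPM 7.60 and 7.57, nearest 6.59 and 6.61) and in ribosomal protein genes (9.42 and 9.47, nearest 8.31 and 8.38). The Y-linked level of ExE wt pool 1 was -0.14, with the nearest other wt pool at 3.21. For 4 lists the difference between homozygous and wt pools changed between tissues by camera at the preset correlation. Among these are the Y-linked genes, whose level depends on the share of males in a pool. Their difference is therefore not shown to be an effect of genotype. The median difference, ExE minus E, was -0.23 for FGF and ERK pathway genes (0.03 in E, -0.42 in ExE), 0.35 for oxidative phosphorylation genes (0.40 and 0.79), 0.26 for ribosomal protein genes (0.51 and 0.73) and 1.02 for Y-linked genes (-0.60 and 0.28). With an estimated correlation 0 lists differed between tissues, and without ExE homozygous pool 3 the medians of oxidative phosphorylation genes and cytosolic ribosomal protein genes were -0.21 and -0.26.

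Splits of the same pools into groups of the same sizes were counted for each comparison. For E homozygous against wt, 1 of 35 splits gave as many as 2 genes, the real one, and the highest other gave 0. That is the lowest share that 35 splits can give, and leaving out any single pool left 0 to 1 genes. Chance is thus made less likely for that count but is not excluded. For the tissues, 1 of 35 splits gave as many as 2347 genes and the highest other gave 0, again the lowest share possible. These splits ignored the pairing of E and ExE pools, so by themselves they do not exclude chance there. For the other 5 comparisons of genotypes within a tissue the real count was 0, which all 35 splits reach by construction, so the splits (highest other 0) decide nothing. For the difference between tissues the real count was also 0, reached by all 60 splits drawn (highest other 3), and decides nothing either. For the number of lists called, chance cannot be excluded in any comparison. That number does not test a given list, since camera compares a list with all other genes. Between tissues, other splits called up to 13 lists while calling 0 genes. In E, 32 of 35 splits gave as many as the real 4 lists for homozygous against wt (highest other 12), 29 of 35 as many as 4 for heterozygous against wt (11) and 16 of 35 as many as 5 for homozygous against heterozygous (9). In ExE the counts were 18 of 35 for the real 5 lists (17), 5 of 35 for 9 (13) and 15 of 35 for 5 (11). For the tissues 31 of 35 splits reached 3 lists (13) and for the difference between tissues 52 of 60 reached 4 (13). Splits that call 3 times the real number of lists point to a structure of the pools other than genotype, or to genes of a list that vary together by more than the preset correlation. Which of these applies was not tested. On simulated counts, with each gene drawn on its own, 0 lists were called at the preset correlation in every comparison. With an estimated correlation 0 lists were called in the real counts.

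The first pattern weighed is the rise of Bin1 and Sirpa in homozygous E. DNA of the stem-cell strain carried along with the trap on chromosome 10, as a cause within that DNA itself, is argued against, since 0 of the 2 genes lie on that chromosome. An effect of such DNA on genes of other chromosomes was not tested. Length and GC bias as the whole cause is argued against, since the smaller of the 2 corrected log2 fold changes was 1.56 ± 0.20 and both genes stayed past the threshold (adjusted p = 0.00637). Visceral endoderm carried over as the whole cause is argued against, since with that level as a covariate the fold change of Sirpa, the smaller one, was 1.60 ± 0.23 against 1.60 ± 0.22 without it, although its wider error ended its call (adjusted p = 0.0671). A response to the loss of TET1 may account for both, as a hypothesis found and tested on the same data. Unlinked strain differences were not tested, nor was blood or decidua carried over into the pools. The mean log2 CPM of blood and immune genes was -1.17 ± 0.82 in wt and 1.08 ± 0.90 in homozygous E. That of decidua genes was 1.31 ± 0.26 and 2.00 ± 0.84 (SD, n = 4 each).

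The second pattern is the higher ribosomal protein list in homozygous pools. The 3 libraries that stood apart on the first principal component had a mean length slope of -0.404 and a mean GC slope of 0.753 per 10%, outside the range of the other libraries, so a length and GC bias of these libraries is a candidate explanation for their distance. Without them the list median was 0.13 in E and 0.24 in ExE, which is 25.2% and 32.7% of the values with them. With the GC and length correction the medians of cytosolic ribosomal protein genes were 0.20 and 0.34 and the camera calls stayed at the preset correlation (adjusted p = 3.10e-10 and 3.52e-25) while at an estimated one the list was not called before or after it (0.696 and 0.382 after), so this bias as the whole cause is neither shown nor excluded. Most of the rise may therefore come from these libraries, and whether their bias arose in amplification or in the embryos was not tested.

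The third pattern is the lower visceral endoderm list in heterozygous E. In E wt pool 1 the list was highest, and 96% of its members (24 of 25) lay above the other wt pools, by a median log2 ratio of 2.68, but that pool was picked by the level of the same list, so this share decides nothing about visceral endoderm carried over at dissection. A single wt pool as the whole cause is argued against by the median alone, which was still -1.45 without that pool. Every other wt pool lay above every heterozygous pool, but this decides nothing. The groups had no overlap with that pool included (lowest wt level 1.47, highest heterozygous level 1.35), so leaving out the highest wt pool could not create one. Levels in homozygous E ranged from 1.37 to 4.69 between pools. Carry-over that varies between pools and an effect of heterozygosity on visceral endoderm both stay open.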

How the results depend on the processing

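The fits without the 3 libraries with steep length slopes and with the GC and length correction were chosen after the data were seen. Of the values of named genes under other settings, 4274 kept direction and side of the threshold, 75 lost the threshold, 46 gained it and 34 turned. Where no reason is given, the cause was not tested.

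With an estimated correlation 0 lists were called in each of the 8 comparisons. DESeq2 called 17 genes in homozygous E against wt (2 by edgeR), 16 in homozygous ExE, 4 in heterozygous E, 18 in heterozygous ExE, 6 and 8 for homozygous against heterozygous in E and ExE, and 3 for the difference between tissues (0 by edgeR in these 6). In homozygous E 1 gene was called with the visceral endoderm covariate, with the Y-linked covariate and in 1 fit of all 23 libraries, 0 against a fold of 1.5, and 4 without the 3 libraries. In homozygous ExE 1 gene was called without a filter, in the fit of all 23 libraries and with the GC and length correction. The fit of all 23 libraries called 20 genes in heterozygous ExE and 2 for homozygous against heterozygous ExE. Between tissues 1159 genes were called against a fold of 1.5, a stricter question by construction, and 3672 without the 3 libraries. Without these the lists called were 9 in homozygous E (4 with them), 9 in homozygous ExE (5), 8 for homozygous against heterozygous E (5) and 8 for the difference between tissues (4). The GC and length correction left 3 lists in homozygous ExE.

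Pool numbers pair E with ExE in 3 of 4 cases per the labels. With the pool number as a block 3509 genes and 8 lists were called between the tissues (2347 and 3 without), and 3542 genes with the GC and length correction added, which left 1 list for the difference between tissues. Between genotypes only the number is known to be shared, and whether litters were is not given in the sources used here. Same-numbered pools correlated at -0.08 to 0.14 for homozygous and wt E, 0.09 to 0.20 for heterozygous and wt E and -0.35 to 0.14 for homozygous and heterozygous E. With that number as a block 0 genes were called in homozygous E (Bin1 at an edgeR adjusted p of 0.398, Sirpa at 0.9996) and 3 lists for homozygous against heterozygous ExE.

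Leaving out each library in turn gave 0 to 1 genes in homozygous E against wt (0 without wt pool 5), 0 to 2 in homozygous ExE (2 without homozygous pool 4), 1502 to 2520 between tissues and 0 to 0 in the other 5. Lists called were 4 to 8 and 3 to 9 for homozygous E and ExE, 3 to 8 and 7 to 10 for heterozygous E and ExE, 6 to 10 and 3 to 7 for homozygous against heterozygous E and ExE, 3 to 10 between tissues and 1 to 8 for the difference between tissues.

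None of the genes that turned had passed the threshold. In homozygous E, Tet2 was at -0.31 and Dnmt1 at 0.0076 with the Y-linked covariate, and Uhrf1 at 0.015 with the GC and length correction. In homozygous ExE, Jmjd8 was at 0.027 with median-ratio size factors, 0.020 with DESeq2, 0.086 and 0.036 with the visceral endoderm and Y-linked covariates and 0.014 in the fit of all 23 libraries. Tet2 was at 0.049 with limma-voom, 0.20 with the block and 0.085 without the 3 libraries, Dnmt3l at -0.011 and -0.050 in the last 2, Dnmt3a at 0.11 with the visceral endoderm covariate and Uhrf1 at 0.033 with the GC and length correction. Without single libraries the ranges were -0.043 to 0.095 (Dnmt3a), -0.026 to 0.35 (Tet3) and -0.10 to 0.030 (Uhrf1) in homozygous E, and -0.61 to 0.20 (Dnmt3a), -0.25 to 0.16 (Jmjd8), -0.34 to 0.13 (Tet2) and -0.050 to 0.38 (Dnmt3l) in homozygous ExE. For the difference between tissues they were -0.14 to 1.26 (Rpl34) and -0.014 to 0.83 (Rps25). At 4 pools per group changes of 2-fold or less in single genes are mostly beyond reach.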

Other observations

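Globin transcripts were seen in epiblast pools, with the highest group means in homozygous E. The globin genes, the 10 permutation tests of list levels, the correlation of Y-linked levels and the test of the 20 genes of heterozygous ExE were chosen after the data were seen. The counts near Tet1 were set before their result was seen. Hbb-bs, a beta-globin gene, had 0 counts in 3 of 4 wt pools (mean 0.0658 ± 0.132 CPM) and was at 0.297 ± 0.291 CPM in heterozygous and 1.77 ± 1.10 CPM in homozygous E (SD, n = 4). Hba-a2, an alpha-globin gene, was at 1.49 ± 2.53 CPM in wt, 1.06 ± 0.515 CPM in heterozygous and 7.62 ± 7.19 CPM in homozygous E. Of 23 blood and immune genes 20 were in the table, and 4 had a mean log2 CPM above 0 over all libraries, the globin genes Hba-a2, Hbb-bs and Hbb-bt and Laptm5. The mean log2 CPM of these 4 was -1.17 ± 0.82 in wt and 1.08 ± 0.90 in homozygous E, with no overlap, which chance gives to 2.86% of genes (exact permutation p = 0.0286, 0.0714 adjusted over 10 such tests). The separation came from the beta-globin copies, since Hba-a2 (up to 5.26 CPM in wt, from 2.23 CPM in homozygous E) and Laptm5 (up to 0.678 CPM in wt, from 0 CPM) overlapped. Hbb-bs reached 0.263 CPM in wt and started at 0.858 CPM in homozygous E, and Hbb-bt reached 0.263 and started at 0.686 CPM. Both thus separated close to the floor of 0.316 to 0.611 CPM. Homozygous pool 1, with the highest level of these 4 genes in E (2.36), also had the highest level of maternal decidua genes there (3.01, against 0.99 to 1.52 in wt). No gene of the list was called by edgeR in that comparison. Of the 10 tests, 4 had no overlap, these being the 4 genes above, decidua genes in homozygous ExE and visceral endoderm markers in heterozygous E against wt and against homozygous E. The other 6 overlapped, with an exact permutation p of 0.114 and 0.0857 for ribosomal protein genes in homozygous E and ExE, 0.0857 for cholesterol and 0.314 for primitive streak genes in homozygous E, 0.943 for visceral endoderm in homozygous E and 0.229 for epiblast markers in heterozygous ExE. In ExE wt, Hbb-bs was at 3.52 ± 2.64 CPM and Hba-a2 at 6.29 ± 5.89 CPM. These copies are nearly identical, and single globin genes are uncertain.

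Decidua transcripts set homozygous ExE apart from wt by level as well. The mean log2 CPM of maternal decidua genes was 0.41 ± 0.51 in wt and 1.95 ± 0.75 in homozygous pools, with no overlap, a separation that chance gives to 5.71% of genes (exact permutation p = 0.0286, 0.0714 adjusted over 10 such tests). Prl8a2 reached 174 CPM in homozygous pool 3, against 13.2 and 17.5 CPM in the other 2 pools, and its highest level in wt was 11.1 CPM. Pool 3, with the steep length slope, also had the highest level of the list (2.78), and without it the camera call remained (median 1.67, adjusted p = 0.029, and adjusted p = 0.841 with an estimated correlation). Ectoplacental cone and trophoblast giant cell markers were at 3.25 to 4.17 in homozygous ExE and 2.10 to 3.28 in wt, without a call (camera adjusted p = 0.128).

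Xaf1, an interferon-inducible gene, was at 91.3, 154 and 136 CPM in E heterozygous 4, E homozygous 3 and ExE homozygous 3, the libraries with steep length slopes, and Zfp935 at 190, 321 and 304 CPM. Group means in ExE wt were 8.61 ± 3.14 CPM for Xaf1 and 34.7 ± 8.18 CPM for Zfp935.

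The 20 genes lower in heterozygous ExE in the fit of all 23 libraries were compared between E and ExE homozygous pools. These pools are not in that contrast but enter the same fit and its estimate of the spread. Genes with a small spread are more easily called in both contrasts, so the share among all genes is not a matched background. Of the 20, 90% (18) were at least 2-fold higher in E at an edgeR adjusted p under 0.05, against 6.13% of all genes, with a median log2 difference of -2.66, ExE minus E. Epiblast cells carried over into some ExE wt pools may account for these genes, as a hypothesis that stays open. Of the 19 of them tested in homozygous against wt ExE, 16 were lower (median log2 fold change -0.72). The genes were picked against the same wt pools, so that fall decides nothing. The epiblast list in ExE wt was at 6.53, 4.56, 6.11 and 5.61 log2 CPM in pools 1, 2, 4 and 5 and at 4.56 to 5.35 in heterozygous pools, while homozygous pools, at up to 6.18, lay within the wt range with a mean of 5.62.

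Strain DNA around the trap was looked for within 20 Mb of Tet1 (42804570 to 82908996 on chromosome 10), Tet1 left out. With 2 genes called in E and 0 in ExE, the test of called genes decides nothing (one-sided Fisher exact p = 1 in both tissues). Of the genes in the window, 9 of 259 (3.47%) had an unadjusted p under 0.05 in homozygous E, against 508 of 12055 elsewhere (4.21%), an odds ratio of 0.818 (95% interval 0.368 to 1.59, one-sided Fisher exact p = 0.765). In ExE it was 24 of 262 (9.16%) against 906 of 12003 (7.55%), an odds ratio of 1.24 (0.772 to 1.89, one-sided Fisher exact p = 0.193). Both upper limits argue against an excess of 2-fold or more, and smaller ones stay open.

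The Y-linked level of same-numbered E and ExE pools was compared over 10 pairs. Pearson's r was 0.291 (permutation p = 0.42) and Spearman's rho 0.515 (permutation p = 0.132), from 100000 resamples, and this was the only relation between levels over pools tested. Without the 2 pairs farthest from the median E level, homozygous 3 and heterozygous 3, r was 0.198. Without wt pair 1, where the level was 4.98 in E and -0.14 in ExE, r was 0.87. Whether ExE wt pool 1 comes from the same litters as E wt pool 1 is open and was not tested, and that pool enters every comparison with ExE wt. The sex of the embryos in each pool is not given in the sources used here.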
